A study of Arabidopsis thaliana with 12 samples.

How the data were processed

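Roots of Arabidopsis thaliana were profiled by RNA sequencing in 12 libraries. The wild type and a line labelled OX3, which overexpresses the soybean vacuolar proton pyrophosphatase gene GmVP2, were grown for 10 days on solid medium with 1250 µM phosphate (normal) or 6.25 µM phosphate (low), per the labels' protocols. Each of the 4 groups held 3 libraries: replicates 2, 3 and 4 for both wild-type groups and for OX3 at normal phosphate, and replicates 1, 2 and 4 for OX3 at low phosphate. Total RNA was purified with CTAB-PBIOZOL and ethanol precipitation and made into libraries with a BGI RNA-Seq kit, per the labels' protocols. Whether the library kit kept the strand, and whether reads or read pairs were counted, is not given in the sources used here.

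The authors deposited 1 table of RPKM values for 25941 genes, with annotation columns. HTSeq 0.6.0 and the TAIR10 genome build are named in the submitters' processing notes, without their role. Of the gene identifiers, 25688 matched the reference gene table of TAIR10.1, and 25683 of these had the same chromosome, start and end there; coordinates are printed as in that assembly. Gene symbols came from the table and the reference gene table.

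Because RPKM is reads divided by gene length and by the library total, whole reads were sought behind the values. A gene length and a library total were found with which 100% of the genes gave whole reads in every library, within 0.01 of a read. The recovered totals ran from 17670350 to 20418541 reads, a ratio of 1.16, and 98.62% of the genes with a single possible length had the length of the union of their exons in TAIR10.1. The floor of 3 reads in a gene of 1 kb corresponded to 0.147 to 0.170 RPKM. The 10 most abundant genes took 3.21% to 4.87% of the reads of a library.

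The main test was limma 3.58.1 in R 4.3.3, with a mean-variance trend, on log2(RPKM + 1). It kept genes with a mean of at least 1 RPKM over all 12 libraries, which left 18910 genes tested and 7031 below the minimum. All 4 groups entered 1 fit, the 5 comparisons were contrasts of it, and a gene was called at a Benjamini-Hochberg adjusted p below 0.05, two-sided. Standard errors are those of limma, SD is between the 3 libraries of a group, and fold changes on the log2 scale include the pseudocount of 1. Since the authors deposited RPKM and no counts are in the table used, edgeR and DESeq2, chosen beforehand for a table of counts, were not run. The limma test chosen beforehand for RPKM took their place. Because the labels do not say that replicates came from separate plants, p-values measure the spread between these samples, which may be technical. Libraries of 1 group differed by more than counting error (chi-square per degree of freedom 2.63 to 10.84), and no pair was identical.

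The gene lists, 30 in number with 536 entries and 514 distinct genes, were fixed before the data were examined, as were 14 gene families defined by words in the annotation, the comparisons, the thresholds and the rule for naming genes. Lists covered phosphate starvation markers, phosphate signalling and transport, acid phosphatases, membrane lipid remodelling, pyrophosphatases, pyrophosphate-linked carbon metabolism, vacuolar and plasma membrane proton ATPases, auxin, root hair, iron deficiency, iron storage, nitrogen, sulfur, glucosinolates, flavonoids, triterpenes, jasmonate, immunity, abscisic acid, hypoxia, heat shock, touch and wounding, shoot photosynthesis, seed storage, root meristem, endodermis, xylem and phloem, and root cap. They were tested with camera of limma, which compares a list with all other tested genes, at a preset inter-gene correlation of 0.01. Adjustment ran over the lists within a comparison, and camera with an estimated correlation and fry were run beside it. Each list also has the number of members called over all tested genes and the number adjusted over the list alone.

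Genes were named by this rule. In each comparison, the 8 highest and 8 lowest log2 fold changes were taken among called genes whose compared groups did not overlap and whose mean was at least 1 RPKM. To these came up to 4 members of each list with the smallest adjusted p, and AVP1, VHP2;1 and VHP2;2, the Arabidopsis relatives of the transgene, whatever their p. Where no gene passed, the 3 with the smallest p were given as not passing. The transgene itself was not measured here, since its sequence is not among the genes of the table.

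Alternatives fixed beforehand were median-ratio size factors, no filter, a pseudocount of 0.1, replicate number as a block, a fit of the 2 compared groups alone, a minimum absolute log2 fold change of 1, and leaving out each library. After the data were seen, these were added: limma voom on the recovered reads, a correction of each library for smooth trends on GC content and gene length, and Fisher exact tests of biological process terms from the annotation columns. The scripts were tested on simulated data in which 200 genes were changed in each comparison. Of the genes changed 1.5-fold, limma recovered 82.1% in the wild-type phosphate comparison (18666 genes in that fit) and 91% in the OX3 phosphate comparison (18719 genes). The genotype comparisons recovered 85.1% at normal (18651 genes) and 85.1% at low phosphate (18829 genes), and the interaction recovered 55.2% (18671 genes). In the interaction 86.6% of 2-fold changes and 98.5% of 4-fold changes were recovered. Of all limma calls, false ones were 15 of 200 in the wild-type and 14 of 207 in the OX3 phosphate comparison. They were 15 of 201 and 12 of 200 between genotypes at normal and low phosphate, and 13 of 173 in the interaction. All simulated genes had 1 common relative variance between libraries, and no library carried a trend on gene length as the real ones did. These shares therefore need not hold for the real fits. Of 30 unchanged lists, camera called 0 in each comparison. The simulated lists were not shown to carry the correlation of real genes, estimated at 0.565 for the ribosomal protein family. Their result therefore cannot show that the preset correlation suits the real lists. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, using numpy 2.4.6 and pandas 2.3.3.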

Results

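Root transcriptomes were measured by RNA sequencing in wild-type Arabidopsis and in OX3, 1 line that overexpresses the soybean vacuolar proton pyrophosphatase GmVP2, at normal and low phosphate. Each of the 4 groups held 3 libraries with recovered totals of 17670350 to 20418541 reads, and values are RPKM as deposited. The first principal component held 82.1% of the variance and parted low from normal phosphate, and the second held 5.2%.

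The relatives of the transgene were examined in all groups. AVP1 (AT1G15690, chromosome 1, 5398926 to 5402733 in TAIR10.1), the main vacuolar proton pyrophosphatase of Arabidopsis, had 175 ± 10.7 RPKM in the wild type and 186.5 ± 4.2 RPKM in OX3 at normal phosphate (SD, n = 3). At low phosphate it had 242 ± 10.8 RPKM in the wild type and 239 ± 9.65 RPKM in OX3. AVP1 rose at low phosphate by 0.47 on the log2 scale in the wild type (limma adjusted p = 1.24e-05) and by 0.36 in OX3 (limma adjusted p = 0.000152). Between genotypes AVP1 did not pass, with log2 differences of 0.09 at normal phosphate (limma adjusted p = 0.336) and -0.01 at low phosphate (0.941). VHP2;2, a Golgi pyrophosphatase, fell at low phosphate by 0.50 in the wild type and by 0.70 in OX3, while VHP2;1 passed in no comparison except OX3 at low phosphate with the GC content and length correction (-0.13, limma adjusted p = 0.0396). Neither VHP2 gene passed between genotypes, with limma adjusted p of 0.289 and 0.702 at normal phosphate and 0.827 and 0.292 at low phosphate for VHP2;2 and VHP2;1.

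The first comparison asked what low phosphate changed in wild-type roots. Genes of phosphate starvation were the strongest to rise. PECP1 (AT1G17710), a phosphatase of phosphocholine and phosphoethanolamine, went from 0.108 ± 0.155 to 488 ± 103 RPKM, a log2 change of 8.78 ± 0.14 (SE, limma adjusted p = 8.13e-15). The non-coding RNA IPS1 (AT3G09922), which sequesters miR399, went from 2.54 ± 0.311 to 1190 ± 179 RPKM (log2 8.39 ± 0.11). SPX1 (AT5G20150), a phosphate sensor that restrains the starvation response, went from 10.0 ± 1.75 to 1030 ± 126 RPKM (log2 6.55 ± 0.11). SPX3 (7.78), the transporter gene OCT1 (7.43), the phosphatase PS2 (7.41), the galactolipid synthase MGD3 (6.73) and AT3G25240 (6.42) completed the 8 largest rises. The largest falls were AT2G36255, annotated as a putative defensin-like gene (-6.06 ± 0.31, from 897 ± 336 to 12.5 ± 4.97 RPKM), the lipid transfer protein gene EARLI1 (-5.22), GSTF14 (-5.05), AT4G11393 (-5.00), AT2G28780 (-4.08), the phosphoethanolamine N-methyltransferase AT1G73600 (-3.69), AT2G22122 (-3.58) and scpl31 (-3.47).

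In total 8692 of 18910 tested genes changed in the wild type, 4601 upward and 4091 downward, with a median absolute log2 change of 0.45 among them. The balance turned with other scalings, to 4311 upward and 4413 downward with median-ratio size factors and to 4187 and 4936 with the GC content and length correction. Of these, 1473 changed by at least 1 on the log2 scale, 846 upward and 627 downward. The 6 compared libraries did not overlap for 53% of the tested genes, where chance gives 10%.

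All 20 of the phosphate starvation markers rose (20 adjusted over the list alone), with a median log2 change of 4.53 and a camera adjusted p of 2.39e-25 (adjusted p = 0.0652 with an estimated correlation). Each marker is also in the list of phosphate signalling, phosphate transport, acid phosphatases, membrane lipid remodelling or pyrophosphate-linked carbon metabolism. Results of these lists and of the markers are therefore not independent. In phosphate transport, 12 of 17 members rose and 0 fell (12 and 1 adjusted over the list alone), led by PHT1;2 (4.07), G3Pp1 (3.85) and the high-affinity transporter PHT1;4, which went from 24.97 to 277 RPKM. Its median was 2.34 (camera adjusted p = 3.19e-09, adjusted p = 0.108 with an estimated correlation). Of the 50-base stretches of PHT1;1 and PHT1;2, 42.5% and 45.6% also occur elsewhere in the genome, against 1.4% for PHT1;3, so the share of reads of PHT1;1 and PHT1;2 is uncertain. In the acid phosphatase list, which also holds the ribonuclease gene RNS1, 15 of 23 rose and 4 fell (15 and 4 adjusted over the list alone). PAP17 (4.44), PAP22 (3.33) and PAP12 (2.37) were among those that rose, and the list median was 1.00 (camera adjusted p = 2.48e-06, adjusted p = 0.108 with an estimated correlation). Of the genes of membrane lipid remodelling, which replace phospholipids by galactolipids and sulfolipids, 17 of 19 rose and 0 fell (17 and 0 adjusted over the list alone), led by SQD2 (4.88) and PLDZ2 (4.62). The median was 2.87 (camera adjusted p = 5.49e-18, adjusted p = 0.0652 with an estimated correlation). Phosphate signalling had 8 members up and 5 down of 17 (8 and 7 adjusted over the list alone), among them SPX2 (2.42), and did not pass (camera adjusted p = 0.0923), its median being 0.05 and its mean 1.71.

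**Figure D1:**
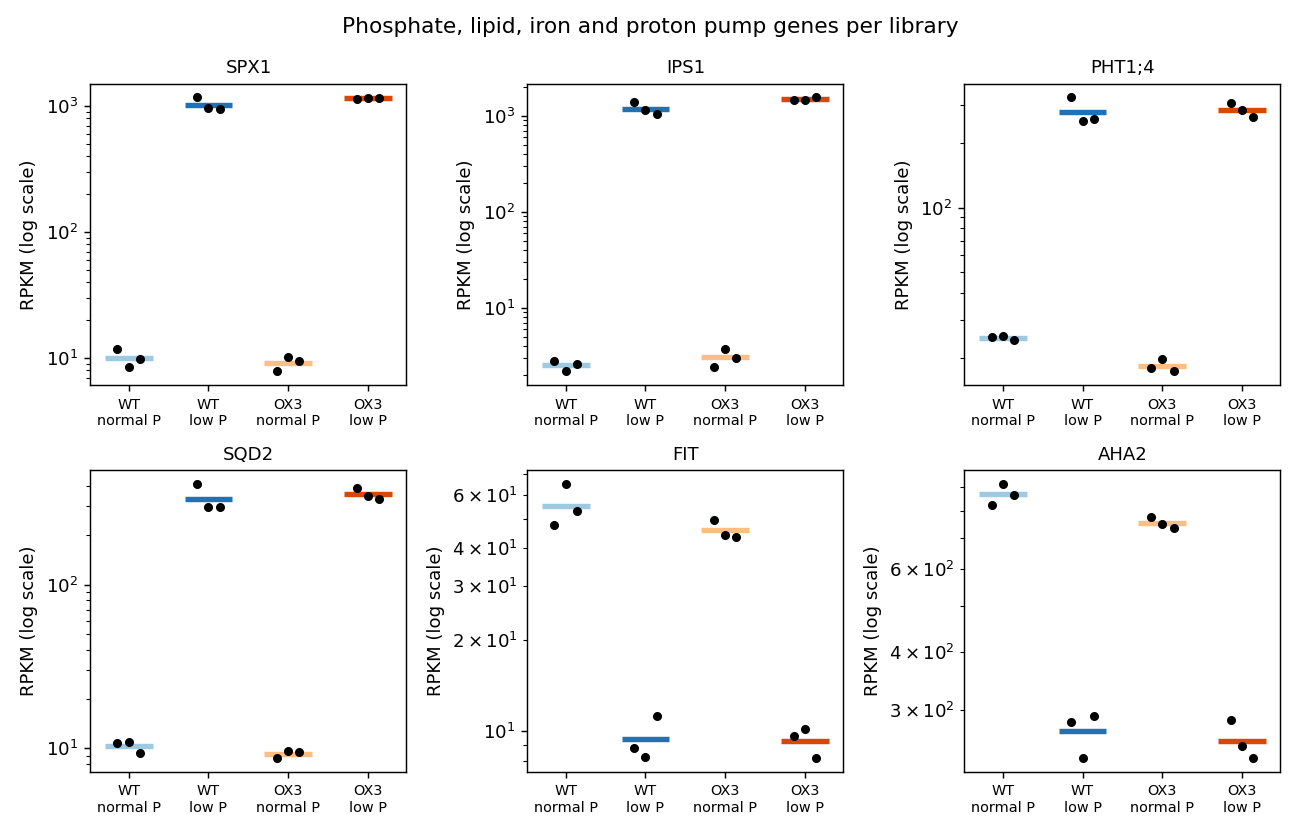
RPKM on a log axis of 6 genes in the 4 groups, with a point for each of the 3 libraries and a line at the group mean. SPX1, IPS1, PHT1;4 and SQD2 lie higher at low phosphate in every library of both genotypes, and FIT and AHA2 lie lower.

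Pyrophosphate and proton pump genes moved in different directions. Of 9 pyrophosphatases 5 rose and 2 fell (5 and 2 adjusted over the list alone), with the soluble PPa4 (1.98) and PPa3 (1.48) up, but the list did not pass (median 0.40, camera adjusted p = 0.0923). In pyrophosphate-linked carbon metabolism, which can spare ATP in glycolysis, 10 of 18 rose and 1 fell (10 and 1 adjusted over the list alone), including SUS4 (2.78), PPCK1 (2.30) and PFP-beta2 (1.68). The median was 0.34 (camera adjusted p = 0.000166, adjusted p = 0.0652 with an estimated correlation). Of 26 subunit genes of the vacuolar proton ATPase 9 fell and 0 rose (9 and 0 adjusted over the list alone), among them VHA-E3 (-0.99) and VHA-c2 (-0.48), with a median of -0.12 (camera adjusted p = 0.0119, adjusted p = 0.39 with an estimated correlation). The plasma membrane proton ATPase list did not pass (3 up and 3 down of 9, 3 and 4 adjusted over the list alone, camera adjusted p = 0.545). Within it, AHA2, the main root proton pump, fell by 1.68, from 868 to 271 RPKM.

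Root hair genes rose, 19 of 22 with 1 down (20 and 1 adjusted over the list alone), among them PRP1 (2.28), PRP3 (1.86) and the regulator RHD6 (1.25). The median was 0.95 (camera adjusted p = 2.15e-06, adjusted p = 0.312 with an estimated correlation). Of the root meristem and cell division genes 14 of 20 rose and 0 fell (15 and 0 adjusted over the list alone), with a median of 0.42 and CDKB2;2 at 0.96 (camera adjusted p = 0.00117, adjusted p = 0.312 with an estimated correlation). In the endodermis and suberin list 10 of 19 rose and 0 fell (11 and 0 adjusted over the list alone), including CASP5 (1.35) and MYB36 (0.79), with a median of 0.29 (camera adjusted p = 0.0119, adjusted p = 0.333 with an estimated correlation). That call was lost without wild-type low phosphate replicate 2 (camera adjusted p = 0.0773). The auxin list did not pass (12 up and 7 down of 32, camera adjusted p = 0.587), nor did xylem and phloem (3 up and 2 down of 10, 0.475) or root cap (2 up and 0 down of 3, 0.182).

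Iron, nitrogen and flavonoid genes were lower at low phosphate. Of the iron deficiency genes 14 of 22 fell and 1 rose (14 and 1 adjusted over the list alone), among them the regulator FIT (-2.43, from 55.2 to 9.41 RPKM) and the nicotianamine synthase NAS1 (-2.39). The median was -1.10 (camera adjusted p = 1.66e-06, adjusted p = 0.0652 with an estimated correlation). Iron storage moved the other way, with 7 of 8 up and 1 down (7 and 1 adjusted over the list alone), the ferritin FER1 going from 251 to 547 RPKM; the median was 0.85 (camera adjusted p = 0.000738, adjusted p = 0.108 with an estimated correlation). Of the nitrogen genes 14 of 19 fell and 5 rose (14 and 5 adjusted over the list alone), led by the ammonium transporter AMT1;3 (-2.89) and the nitrate transporter NRT1.1 (-2.16), with a median of -1.09 (camera adjusted p = 2.6e-05, adjusted p = 0.155 with an estimated correlation). Flavonoid and anthocyanin genes fell in 13 of 16 cases and rose in 1 (13 and 1 adjusted over the list alone), including F3pH (-1.85) and CHI (-1.54). The median was -1.35 (camera adjusted p = 2.42e-05, adjusted p = 0.298 with an estimated correlation). The sulfur list did not pass (9 up and 5 down of 15, camera adjusted p = 0.104), although SULTR1;3 rose by 4.18 and SULTR1;2 fell by 1.46. Glucosinolate synthesis (5 up and 8 down of 21, camera adjusted p = 0.201) and triterpenes (5 up and 3 down of 8, 0.452) did not pass either.

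Lists of shoot photosynthesis and of handling were examined next. Of 26 shoot photosynthesis genes 21 fell and 2 rose (22 and 2 adjusted over the list alone), including LHCB1.3 (from 223 to 85.5 RPKM) and RBCS1A (from 146 to 57.4 RPKM). The median was -0.79 (camera adjusted p = 4.34e-09, adjusted p = 0.158 with an estimated correlation). Of the 50-base stretches of LHCB1.3 17% also occur elsewhere in the genome, so its value is uncertain, against 0% for RBCS1A. Of 10 shoot markers outside photosynthesis, the 6 under 1 RPKM on average had 43 summed reads at normal and 137 at low phosphate (66 and 82 in OX3). Of the other 4, CER1 rose by 0.67 (limma adjusted p = 0.000853), and ATML1 (0.16), PDF1 (-0.12) and FDH (-0.18) did not pass. Of 8 tested clock genes, FKF1 (1.66), GI (1.37), PRR5 (0.68) and TOC1 (0.26) rose and RVE8 (-0.46) fell (limma adjusted p up to 0.00305). LHY (-0.31), ELF4 (0.21) and LUX (-0.07) did not pass. In OX3 these called genes moved in the same directions, and ELF4 rose too (0.27, limma adjusted p = 0.0158). A harvest of the phosphate groups at another time of day was therefore not told apart from an effect of low phosphate. Abscisic acid and dehydration genes rose in 6 of 10 cases and fell in 1 (6 and 2 adjusted over the list alone), with KIN1 at 1.75 and a median of 1.16 (camera adjusted p = 0.0136, adjusted p = 0.265 with an estimated correlation). Of the touch and wounding genes 5 of 6 rose and 1 fell (5 and 1 adjusted over the list alone), with a median of 0.77 (camera adjusted p = 0.0176, adjusted p = 0.108 with an estimated correlation). Heat shock genes fell in 5 of 8 cases and rose in 1 (5 and 1 adjusted over the list alone), with HSP70-4 at -1.60 and a median of -0.86 (camera adjusted p = 0.0319, adjusted p = 0.254 with an estimated correlation). That call was lost without wild-type normal phosphate replicate 2 (camera adjusted p = 0.0521) and with the GC content and length correction (0.0589). Jasmonate (8 up and 2 down of 14, camera adjusted p = 0.067), immunity (5 and 3 of 10, 0.141), hypoxia (4 and 2 of 11, 0.333) and the single tested seed storage gene SESA4 (log2 0.61, 0.394) did not pass as lists, while AOC1 rose by 3.24 and VSP2 fell by 2.56 within jasmonate.

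The second comparison asked the same of OX3, where the starvation genes rose again. PECP1 (8.82), IPS1 (8.52), SPX3 (7.66), OCT1 (7.54), PS2 (7.17), MGD3 (6.93), SPX1 (6.84) and AT5G20790 (6.78) had the largest rises, IPS1 going from 3.09 ± 0.660 to 1489 ± 62.6 RPKM (SD, n = 3). AT2G36255 (-6.35), GSTF14 (-4.97), AT4G11393 (-4.88), EARLI1 (-4.78), AT2G28780 (-4.0), AT1G73600 (-3.77) and the anthocyanin genes DFR (-3.83) and LDOX (-3.74) fell most. In OX3 8895 genes changed, 4397 upward and 4498 downward (4561 and 4327 with median-ratio size factors, 4286 and 5147 with the GC content and length correction), with 1490 of them by at least 1 on the log2 scale (856 and 634). The 6 libraries did not overlap for 57.4% of the genes, where chance gives 10%.

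All 20 starvation markers rose in OX3 (20 adjusted over the list alone; median 4.64, camera adjusted p = 9.23e-27, adjusted p = 0.0682 with an estimated correlation). Phosphate transport had 15 members up and 1 down (15 and 1 adjusted over the list alone; 2.46, 2.14e-11, adjusted p = 0.0757 with an estimated correlation), with PHT1;4 going from 18.5 to 284 RPKM. Membrane lipid genes had 17 up and 0 down (18 and 0 adjusted over the list alone; 3.09, 7.33e-19, adjusted p = 0.0682 with an estimated correlation). Acid phosphatases had 15 up and 4 down (16 and 4 adjusted over the list alone; 1.07, 4.87e-07, adjusted p = 0.0757 with an estimated correlation). Pyrophosphate-linked carbon metabolism had 9 up and 1 down (10 and 1 adjusted over the list alone; 0.27, 0.000112, adjusted p = 0.0651 with an estimated correlation), and the vacuolar proton ATPase had 0 up and 11 down (0 and 9 adjusted over the list alone; -0.13, 0.00475, adjusted p = 0.386 with an estimated correlation). Root hair genes had 20 up and 1 down (20 and 1 adjusted over the list alone; 0.99, 1.5e-06, adjusted p = 0.316 with an estimated correlation).

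Iron deficiency genes in OX3 had 2 up and 14 down (2 and 14 adjusted over the list alone; median -1.01, camera adjusted p = 2.7e-05, adjusted p = 0.0757 with an estimated correlation), FIT changing by -2.18. Iron storage had 7 up and 1 down (7 and 1 adjusted over the list alone; 0.76, 0.000486, adjusted p = 0.0757 with an estimated correlation). Nitrogen genes had 5 up and 14 down (5 and 14 adjusted over the list alone; -1.09, 0.000112, adjusted p = 0.177 with an estimated correlation), with NIR1 at -2.14. Flavonoid genes had 2 up and 13 down (2 and 13 adjusted over the list alone; -1.55, 2.42e-05, adjusted p = 0.294 with an estimated correlation), with TT19 at -3.01. Abscisic acid genes had 7 up and 2 down (7 and 2 adjusted over the list alone; 0.96, 0.00454, adjusted p = 0.177 with an estimated correlation). Photosynthesis genes had 0 up and 22 down (0 and 22 adjusted over the list alone; -1.15, 5.16e-13, adjusted p = 0.0925 with an estimated correlation), LHCB1.3 going from 344 to 100.5 RPKM. Endodermis genes had 14 up and 0 down (15 and 0 adjusted over the list alone; 0.47, 2.8e-05, adjusted p = 0.177 with an estimated correlation). Meristem genes had 9 up and 1 down (10 and 1 adjusted over the list alone; 0.21, 0.0327, adjusted p = 0.479 with an estimated correlation), a call lost without OX3 low phosphate replicate 2 (0.0599). Touch and wounding (4 up and 1 down of 6, 4 and 1 adjusted over the list alone; median 0.56, camera adjusted p = 0.103) and heat shock (1 up and 5 down of 8, 1 and 5 adjusted over the list alone; -0.64, 0.0876), which passed in the wild type, did not pass in OX3. In hypoxia, which did not pass (camera adjusted p = 0.836), the median was -0.23 and the mean 0.09, and in glucosinolate synthesis (0.802) the median of 0.04 and the test differed in sign.

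The responses of both genotypes were then overlapped. PECP1, IPS1, SPX3, OCT1, PS2, MGD3 and SPX1 were among the 8 largest rises in each. In both genotypes 3598 genes rose, where 1069.8 were expected, and 3418 fell, where 973.1 were expected, while 5 genes went in opposite directions. These, looked up after the count was seen, were ASPGB1, AT1G14205, CYB561D, PDC1 and MYB77, each higher at low phosphate in the wild type (0.20 to 0.43) and lower in OX3 (-0.34 to -0.23). None of them passed the test of a difference between the responses. The count of opposite genes was 2 with voom, 0 without OX3 low phosphate replicate 2 and 15 without wild-type low phosphate replicate 2. Across genes, which are not independent replicates, the log2 changes had a Pearson correlation of 0.959, a Spearman correlation of 0.886 and a slope of 0.965. Of the genes changed in the wild type 98.3% had the same sign in OX3. With an absolute log2 change of at least 1 in both, 1251 genes moved in the same direction.

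**Figure D2:**
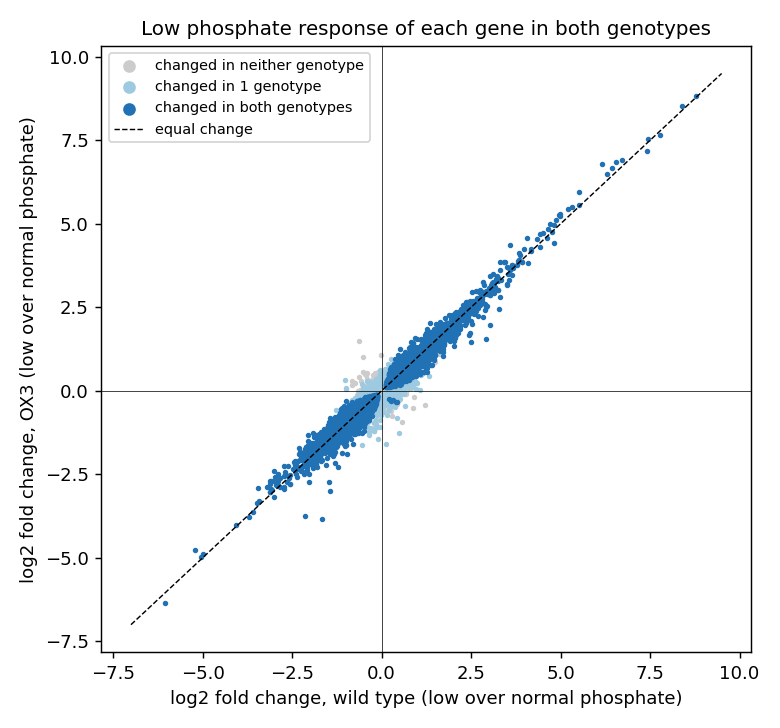
Log2 fold change of low over normal phosphate in the wild type (x axis) and OX3 (y axis), with a point for each of 18910 genes coloured by the number of genotypes in which it changed and a dashed line of equal change. Points lie along the dashed line, with a slope of 0.965.

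**Figure D3:**
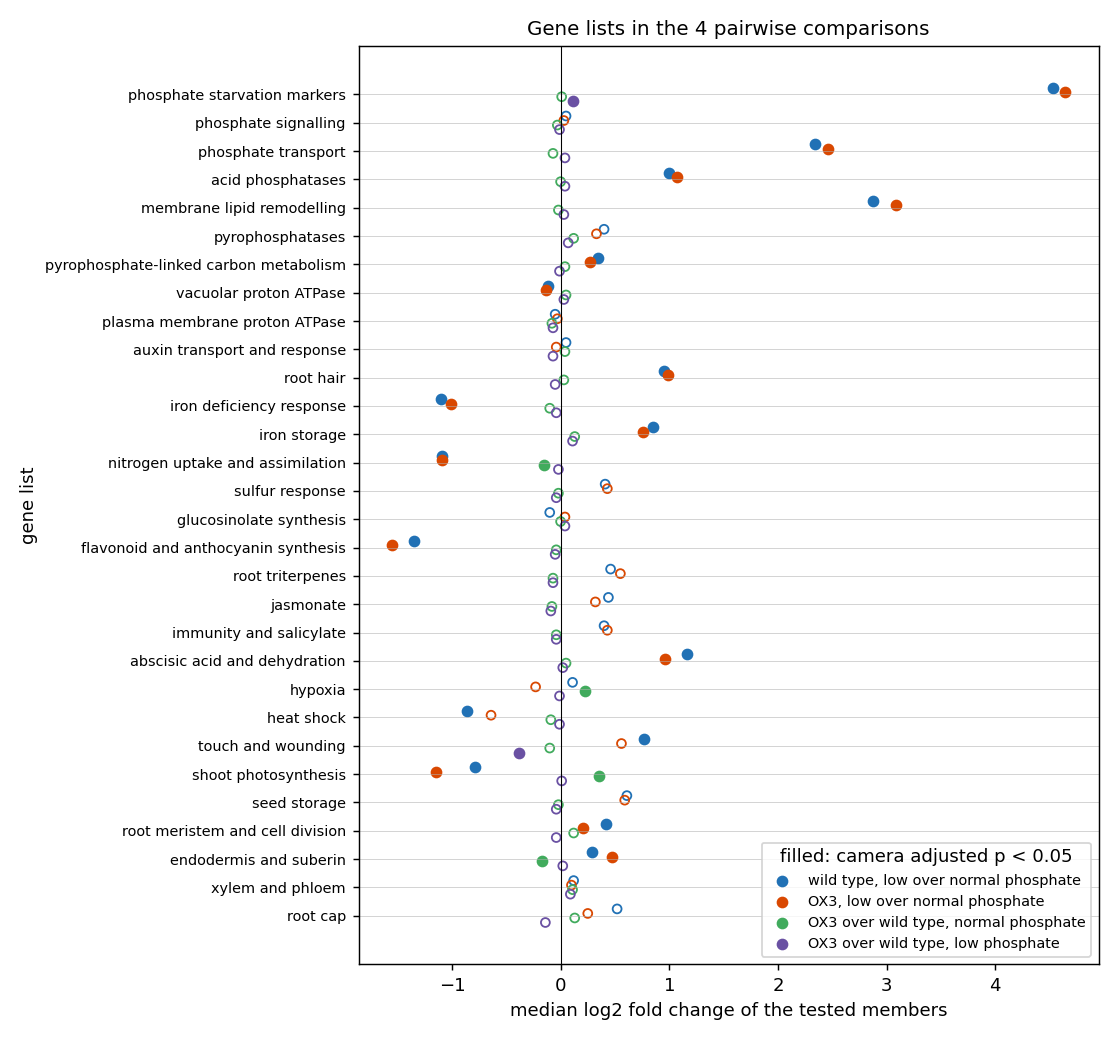
Median log2 fold change of the tested members (x axis) of 30 gene lists (y axis) in 4 pairwise comparisons, filled where camera gave an adjusted p below the threshold. The phosphate comparisons span -1.55 to 4.64, and the genotype comparisons stay within -0.38 and 0.35.

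The third comparison asked how OX3 differed from the wild type at normal phosphate. AT3G29633 (chromosome 3, 11452509 to 11453528), a gene without a described function in the annotation, was at 49.7 ± 1.82 RPKM in OX3 and 0.787 ± 0.155 RPKM in the wild type (SD, n = 3), a log2 difference of 4.83 ± 0.23 (SE, limma adjusted p = 1.05e-07). AT1G15290 (chromosome 1, 5256870 to 5265155), annotated as Protein TSS, was at 22.6 ± 1.45 against 8.67 ± 0.488 RPKM (1.29 ± 0.11, limma adjusted p = 0.000149). DOT1, which encodes a glycine-rich protein, was lower in OX3, at 148 ± 6.68 against 265 ± 46.5 RPKM (-0.83 ± 0.10, limma adjusted p = 0.0027). Genes of light harvesting and carbon fixation were higher, LHCB1.3 at 344 against 223 RPKM (0.62 ± 0.09) and RBCS1A at 218 against 146 RPKM (0.58 ± 0.08). The anthocyanin genes DFR (2.11 ± 0.38, at 22.9 ± 12.7 against 4.76 ± 3.41 RPKM), LDOX (1.75), TT19 (1.48) and UF3GT (1.3) were higher too, with wide spread. In a term test chosen after the data were seen, anthocyanin synthesis had 5 of 18 genes higher where 0.3 were expected (Fisher exact test, adjusted p = 0.000833).

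GRXC14 (1.08) and JAL41 (1.01) completed the 8 largest rises. QQS (-1.20), a gene of carbon and nitrogen allocation, AT3G24080 (-1.10), AT1G75945 (-0.94), AT3G49601 (-0.88), AT5G46730 (-0.83), AT3G05170 (-0.83) and AT5G60030 (-0.82) joined DOT1 among the largest falls. In total 587 genes differed, 259 higher and 328 lower in OX3, of which 10 by at least 1 on the log2 scale (8 and 2). With median-ratio size factors the split was 206 higher and 400 lower. The 6 libraries did not overlap for 32.8% of the genes, where chance gives 10%. The count changed when single libraries were left out: it was 1059, 66 and 39 without wild-type replicate 2, 3 or 4, and 369, 37 and 8 without OX3 replicate 2, 3 or 4. Genes at an unadjusted p below 0.05 (limma) numbered 4559 in the full fit and 3020 to 4759 in these fits. How much of the change came from the smaller group was not tested. The compared groups did not overlap for any of the 587 genes, so leaving out a library could not change their sign, which shows no stability. In all 6 fits 8 genes were called, namely AT3G29633, AT1G15290, AT4G09240, AT1G19330, AT4G38710, AT1G47970, AT3G18790 and DOT1. DFR and LDOX were called in 2 of the 6, with adjusted p of 0.0558 and 0.0627 without wild-type replicate 3, 0.0727 and 0.0823 without wild-type replicate 4, 0.0624 and 0.062 without OX3 replicate 3, and 0.0785 and 0.0825 without OX3 replicate 4. LHCB1.3, RBCS1A and QQS each had 0.0545 without OX3 replicate 4 and were called in the other fits. TT19 and UF3GT were lost without wild-type replicate 4 (0.0611 and 0.0698) and OX3 replicates 3 (0.062 and 0.0556) and 4 (0.0716 and 0.079). The other genes named as the largest rises and falls were each lost at least without OX3 replicate 4, with adjusted p up to 0.158 over the 6 fits. Without a filter DFR (0.0511), LDOX (0.0531), AT3G24080 (0.0506), AT3G05170 (0.0639) and AT5G60030 (0.0767) were lost, and GRXC14 with a pseudocount of 0.1 (0.0601).

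The genotype differences varied with gene length. Across genes, the log2 difference had a Spearman correlation with gene length of -0.404 at normal and -0.412 at low phosphate, against -0.012 and 0.03 in the wild-type and OX3 phosphate comparisons. Within single libraries, the correlation of length with the deviation from the gene's mean was 0.071 to 0.209 in the 6 wild-type libraries and -0.227 to -0.075 in OX3 at normal phosphate. In OX3 at low phosphate it was 0.013, -0.038 and -0.326 in replicates 1, 2 and 4, so the trend there rested mainly on replicate 4. The median length was 2477.5 bases among genes lower in OX3, 1295 among genes higher and 1755.5 among all tested. With the GC content and length correction, chosen after the data were seen, 296 genes were called (117 higher and 179 lower), of which 249 were among the 587. The labels do not say whether OX3 and wild-type libraries were prepared together, so a difference of preparation that followed genotype is not excluded for the 587 genes.

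Of 26 shoot photosynthesis genes 12 were higher in OX3 and 0 lower (17 and 0 adjusted over the list alone), with FBA1 (0.56) and LHCB5 (0.51) beside LHCB1.3 and RBCS1A, a median of 0.35 and a camera adjusted p of 2.02e-13 (adjusted p = 0.555 with an estimated correlation). Summed reads of 6 shoot markers outside photosynthesis, each under 1 RPKM on average, had a ratio of OX3 to wild type of 1.504 (95% interval 0.6703 to 3.375) at normal and 0.621 (0.3555 to 1.085) at low phosphate. As a list, endodermis genes had a median of -0.17 (0 up and 0 down of 19, 0 and 1 adjusted over the list alone; camera adjusted p = 0.00242, adjusted p = 0.555 with an estimated correlation). The nitrogen list had a median of -0.15, with NRT3.1 (-0.31) the 1 member called (0 up and 5 down adjusted over the list alone; camera adjusted p = 0.0134, adjusted p = 0.555 with an estimated correlation). The hypoxia list had a median of 0.22, with LBD41 (0.41) the 1 member called (5 up and 0 down adjusted over the list alone; camera adjusted p = 0.0134, adjusted p = 0.555 with an estimated correlation). The hypoxia call was lost without wild-type replicate 3 (0.0955). With fry the endodermis (adjusted p = 0.171), nitrogen (0.174) and hypoxia (0.171) calls were lost. With the GC content and length correction the nitrogen median was -0.07.

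Single members of these lists were lost in several fits. NRT3.1 was lost without wild-type replicates 3 (limma adjusted p = 0.135) and 4 (0.157), OX3 replicates 3 (0.181) and 4 (0.141), a filter (0.0806) and with a pseudocount of 0.1 (0.0507). LHCB5 was lost without wild-type replicates 3 (0.0633) and 4 (0.0874) and OX3 replicates 3 (0.0632) and 4 (0.0764), and FBA1 without wild-type replicate 3 (0.0559) and OX3 replicate 4 (0.0676). LBD41 was lost without wild-type replicates 3 (0.0561) and 4 (0.0551) and OX3 replicates 3 (0.0556) and 4 (0.0618).

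Phosphate genes were compared at normal phosphate as well. Of the 20 starvation markers 1 was lower in OX3 and 0 higher, with a median of 0.01 (camera adjusted p = 0.732), and that member was PHT1;4, at 18.5 against 24.97 RPKM (-0.42 ± 0.09, limma adjusted p = 0.0285). PHT1;4 was called again in 1 of the 6 fits with a library left out, without wild-type replicate 2; its adjusted p in the others was 0.0963 and 0.101 without wild-type replicates 3 and 4, and 0.0628, 0.0763 and 0.119 without OX3 replicates 2, 3 and 4. PHT1;4 was also lost without a filter (0.0603) and with the GC content and length correction (-0.36, limma adjusted p = 0.0566). The acid phosphatase list did not pass (1 up and 0 down of 23, 1 and 0 adjusted over the list alone, median 0, camera adjusted p = 0.89), its called member being PAP3 (AT1G14700), higher in OX3 at 3.015 against 1.637 RPKM (0.61 ± 0.15, limma adjusted p = 0.0473). PAP3 was called again in 1 of the 6 fits with a library left out, without wild-type replicate 2, and was lost without a filter (0.074), with a pseudocount of 0.1 (0.118) and with the GC content and length correction (0.0777). Phosphate transport did not pass (0 up and 1 down of 17, 0 and 3 adjusted over the list alone, camera adjusted p = 0.0979), nor did the pyrophosphatases (0 and 0 of 9, 2 and 0 adjusted over the list alone, 0.136). The flavonoid list, with 5 members higher and 0 lower of 16 (6 and 1 adjusted over the list alone), had a median of -0.04 and a mean of 0.40 and did not pass (camera adjusted p = 0.601).

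**Figure D4:**
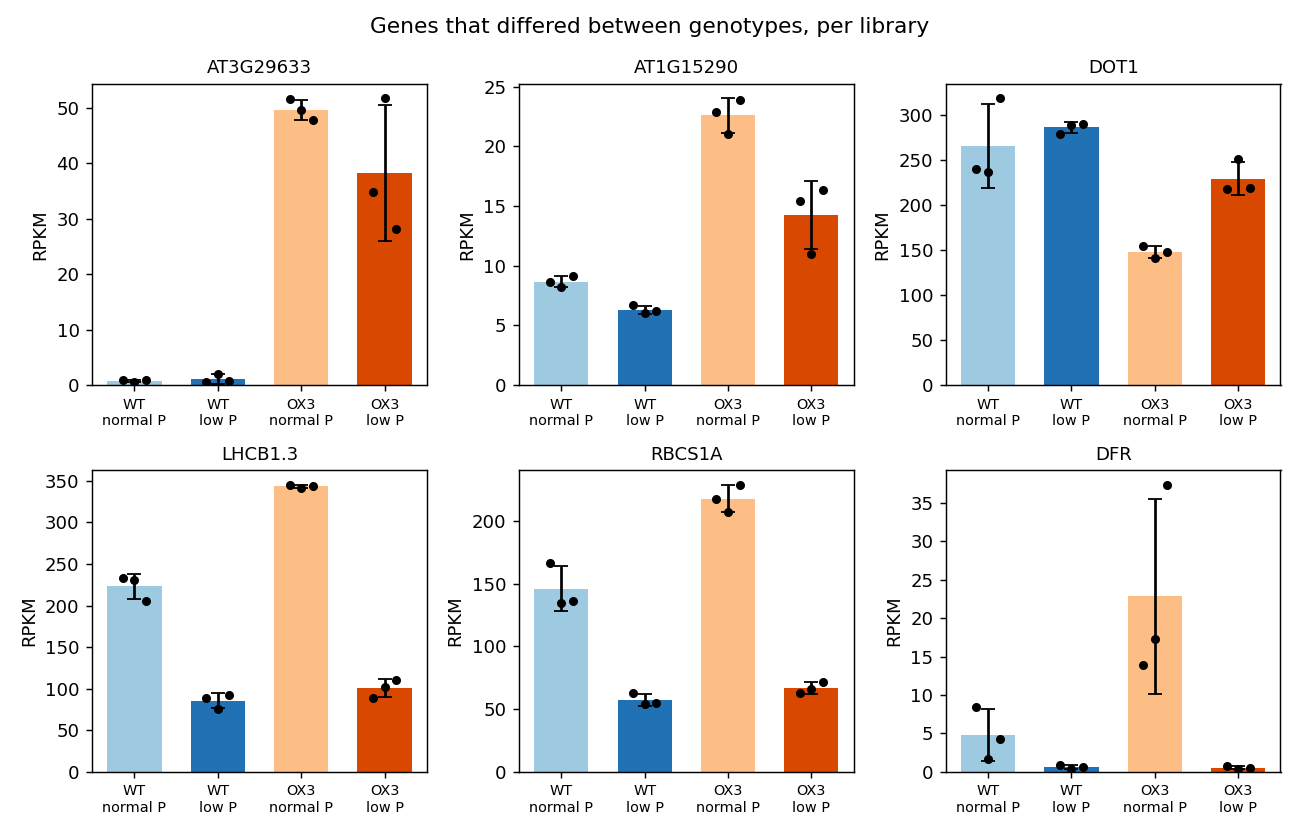
RPKM of 6 genes in the 4 groups, with a bar at the mean, an error bar of 1 SD and a point for each of the 3 libraries. AT3G29633 and AT1G15290 lie higher in every OX3 library at both phosphate levels, and DFR at normal phosphate spreads more between libraries than the other genes.

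The fourth comparison set OX3 against the wild type at low phosphate, where 8 genes differed. AT3G29633 (4.28 ± 0.23, limma adjusted p = 5.35e-07), the lectin gene JAL41 (1.24, at 61.3 against 25.5 RPKM) and AT1G15290 (1.04) were higher in OX3. PHI-1 (-0.94 ± 0.10, at 8.56 ± 0.889 against 17.43 ± 2.87 RPKM), the auxin-related regulator MYB77 (-0.72), ARP9 (-0.67), EXO (-0.65) and NAD-ME2 (-0.33) were lower, with limma adjusted p up to 0.0482. With median-ratio size factors 5 genes were called, 3 higher and 2 lower. The 6 libraries did not overlap for 17.1% of the genes, where chance gives 10%. Without wild-type replicate 2 the count was 196, without wild-type replicate 4 and OX3 replicate 1 it was 4 each, and without OX3 replicate 4 it was 3. AT3G29633, AT1G15290 and PHI-1 were called in all 6 fits with a library left out. JAL41 was lost without wild-type replicate 4 (0.0635) and OX3 replicates 1 (0.058) and 4 (0.114), and ARP9 without OX3 replicates 1 (0.058) and 4 (0.0785). MYB77, EXO and NAD-ME2 were lost without wild-type replicate 4 or any OX3 replicate, and EXO and NAD-ME2 also without wild-type replicate 3, with adjusted p from 0.058 to 0.377. EXO (-0.68) and NAD-ME2 (-0.26) were also lost with the GC content and length correction (limma adjusted p = 0.0611 each), and MYB77 (0.0505), EXO (0.0521) and NAD-ME2 (0.0521) with median-ratio size factors. Without a filter JAL41 (0.0544), MYB77 (0.0808) and EXO (0.126) were lost, and EXO also with a pseudocount of 0.1 (0.0561). In a fit of the 2 groups AT1G15290 and PHI-1 had 0.0567 each, ARP9 0.0863, and MYB77, EXO and NAD-ME2 0.388 each.

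As a list, touch and wounding genes had a median of -0.38 in OX3 against the wild type at low phosphate, with 0 of 6 members called (0 up and 4 down adjusted over the list alone; camera adjusted p = 0.000595, adjusted p = 0.0711 with an estimated correlation). TCH4 had a log2 difference of -0.65 and WRKY40 of -0.56. Starvation markers had a median of 0.11 (0 up and 0 down of 20, 1 and 0 adjusted over the list alone; camera adjusted p = 0.00369, adjusted p = 0.949 with an estimated correlation), with IPS1 at 0.33 and PPCK1 at 0.37. That call was lost without wild-type replicates 3 (0.0851) or 4 (0.207) and without OX3 replicate 1 (0.194), and with fry (0.769). Photosynthesis genes had a median of 0.01 (camera adjusted p = 0.473). Of the 587 genes that differed at normal phosphate 526, or 89.6%, had the same sign at low phosphate. AT3G29633, AT1G15290 and JAL41 were called higher at both levels and ARP9 lower (-0.54 and -0.67). Across genes the genotype differences at both levels had a Pearson correlation of 0.445 and a Spearman correlation of 0.45, with 4 genes called in the same direction. Both differences also fell with gene length (Spearman correlations of -0.404 at normal and -0.412 at low phosphate). Such a shared trend can raise these correlations and the share of equal signs, by an amount that was not tested. The overlap of called genes was 43 without wild-type low phosphate replicate 2 and 2 without any of OX3 normal phosphate replicates 3 and 4 or OX3 low phosphate replicates 1 and 4.

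The fifth comparison asked whether the response to low phosphate differed between genotypes. No gene passed: limma called 0, with 1351 genes at an unadjusted p below 0.05 (7.1%), and voom on the recovered reads called 0, with 1284. The smallest p belonged to CCL (-0.67), HSP23.5 (0.75) and STO (0.58), none passing (limma adjusted p = 0.379). Without OX3 low phosphate replicate 4 the count was 1, HSP23.5 (limma adjusted p = 0.0162). As a list, photosynthesis genes fell further in OX3 than in the wild type, by a median of -0.35 (0 up and 13 down of 26 adjusted over the list alone; camera adjusted p = 7.1e-14, adjusted p = 0.486 with an estimated correlation). Between genotypes the median of the photosynthesis list was 0.35 at normal and 0.01 at low phosphate, in the same libraries. Its difference of the responses is therefore not independent of the result at normal phosphate. The gene AVP1 had a difference of -0.11 (limma adjusted p = 0.793).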

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

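The tests chosen only after the result was seen were those of shoot tissue, of time of day, of GC content and gene length on the mRNA processing genes and of 1 library carrying their difference, which was also replaced by a test on the low phosphate libraries after its own values and the low phosphate median were seen. The purine measure was chosen after seeing which genes were lower in OX3, with its bound set before its values were computed. The GC content and length correction, the voom fit and the term tests were also added after the data were seen.

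The difference of the low phosphate response between genotypes passed camera for 6 lists, although limma called 0 single genes (1351 at an unadjusted p below 0.05; voom 0 and 1284). Median log2 differences were -0.35 for shoot photosynthesis (adjusted p = 7.1e-14) and 0.15 for endodermis and suberin (0.000264). They were 0.12 for phosphate transport (0.00061), 0.14 for phosphate starvation markers (0.00127), which share members with phosphate transport, -0.12 for hypoxia (0.00559) and -0.08 for root meristem and cell division (0.0229). With an estimated correlation none of the 6 passed (adjusted p = 0.486, 0.486, 0.486, 0.713, 0.486 and 0.713 in that order), and with fry the lowest adjusted p of the 6 was 0.199. The starvation marker call was lost without wild-type normal phosphate replicate 2 (0.0514), wild-type low phosphate replicate 4 (0.0781) and OX3 normal phosphate replicate 2 (0.103), and the hypoxia call without wild-type normal phosphate replicate 3 (0.0658). The meristem call was lost without wild-type normal phosphate replicate 4 (0.0772), wild-type low phosphate replicates 3 (0.225) and 4 (0.0703), and OX3 low phosphate replicates 1 (0.0818) and 4 (0.0504). Photosynthesis, endodermis and hypoxia also passed between genotypes at normal phosphate (medians 0.35, -0.17 and 0.22), with medians of 0.01, 0.02 and -0.01 at low phosphate. Their calls here use the same libraries and are not independent of those at normal phosphate.

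Photosynthesis genes were higher in OX3 than in the wild type at normal phosphate, with a list median of 0.35 (camera adjusted p = 2.02e-13, adjusted p = 0.555 with an estimated correlation). Against GC content or gene length bias, the median was 0.35 after the correction and all 12 called members were called again. Against harvest at another time of day, 1 of 8 tested clock genes was called (GI, -0.73) and the morning and evening medians were -0.02 and -0.08. The morning median rested on LHY and RVE8 alone, at 1.705 and 3.423 RPKM in the wild type at normal phosphate, since CCA1 and PRR9 were not tested. These clock values cover the genotype comparison only, and clock genes did change between phosphate levels. Shoot tissue carried into the root samples cannot be told apart from a change within roots: the summed reads of 6 shoot markers with a mean under 1 RPKM had a ratio of 1.504 (95% interval 0.6703 to 3.375), which spans both 1 and the list's median fold of 1.27, on 43 reads in the wild type and 66 in OX3. A first form of that test used all 10 markers and gave 0.8117 (0.6132 to 1.074), but was replaced after it was seen because PDF1 and FDH, with a high root baseline, made up most of its reads. A biological difference of the line stays open and untested, since 1 transgenic line does not part the transgene from other features of that line.

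AT3G29633 and AT1G15290 were higher in OX3 at both phosphate levels. Against reads shared between paralogs or pseudogenes, 0% of the 50-base stretches of either gene model occurred elsewhere in the genome. A change that covers the neighbourhood of each locus cannot be told apart from one of the gene alone: the 13 tested genes within 20 kb had a median log2 difference of -0.1 and 0 were called higher, but AT1G15280 (-0.39) and MBD10 (-0.80) beside AT1G15290 were called lower, and AT3G29633 had 1 tested neighbour. The transgene's insertion site was not examined here, so an effect of the insertion, a variant of the line and an effect of GmVP2 all stay open.

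Among genes lower in OX3 at normal phosphate 21 of 217 tested mRNA processing genes were called, where 4 were expected (Fisher exact test, adjusted p = 4.58e-07). As for 1 library carrying the difference, the 21 genes all had a negative log2 difference at low phosphate, with a median of -0.23 (95% interval between libraries -0.44 to -0.01). Without wild-type or OX3 low phosphate replicate 4 that median was -0.16 or -0.17, with 21 genes negative each time. These genes were long, at a median of 3013 bases against 1755.5 for all tested genes. The genotype difference at low phosphate fell with gene length (Spearman -0.412), so negative values there would also follow from that trend. The low phosphate libraries therefore cannot decide whether 1 library carried the difference at normal phosphate. The 6 low phosphate libraries entered the choice of the genes only through the shared variance and the filter. At normal phosphate the median of -0.42 was at weakest -0.37 with a library left out, but the genes were chosen in those libraries, so this cannot decide. The calls there numbered 21, 3 and 1 without wild-type replicates 2, 3 and 4, and 15, 0 and 0 without OX3 replicates 2, 3 and 4. GC content or gene length bias may account for part of the difference. The correction moved the median at normal phosphate to -0.28 (range from -0.25 to -0.88 before, from -0.16 to -0.85 after). After it 10 of 21 were called again, the median of the 11 others moving from -0.38 to -0.22 with no larger standard error in any. A bias against purine-rich sequence also cannot be told apart, because the log2 difference fell with the highest A and G share in a 50-base window at normal phosphate (Spearman -0.206) but less at low phosphate (-0.169), short of the bound set beforehand. The tests of 1 library and of GC content and length were at first run on all 217 genes, where the median was -0.05, -0.02 after the correction and -0.04 to -0.07 with a library left out, and were moved to the 21 called genes after those values were seen.

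Other splits of the libraries were compared with the real one. For the phosphate comparisons 1 of 10 splits, the real one, gave as many genes (8692 in the wild type and 8895 in OX3; highest other 0 each). For the genotype comparisons it was also 1 of 10 (587 at normal phosphate, highest other 0; 8 at low phosphate, highest other 1). Splits of 3 against 3 are too few for a share under 0.05. Every other split also mixed the 2 real groups, so that their difference became spread within groups. The counts of the other splits therefore do not show what chance gives. For the difference of the responses 21 of 100 splits had as many genes at an unadjusted p below 0.05 as the real 1351, so chance is not excluded over all splits; the highest other had 4034, which points to a structure of the samples. As looked up after that value was seen, 1 of 42 other splits with equal shares of OX3 libraries at both phosphate levels was as large as the real one (median 515, range 250 to 1407). Of those with unequal shares, where the genotype difference enters the comparison, 10 of 46 that differed by 1 library (median 899.5) and 9 of 11 that differed by 2 (1737) were as large. The 42 splits with equal shares also mixed wild-type and OX3 libraries within groups, so that the genotype difference became spread. Their counts therefore do not show what chance gives either, and 1 of 42 is no support for a difference of the responses.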

How the results depend on the processing

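The voom fit, the GC content and length correction, all alternatives of the gene families and the voom, block and left-out values of the overlaps were chosen after the data were seen; edgeR and DESeq2 were not run, since the values are RPKM. A minimum absolute log2 change of 1 left 1473, 1490, 10 and 3 genes in the phosphate comparisons of the wild type and OX3 and the genotype comparisons at normal and low phosphate, and 1251 genes in the overlap of the responses, by its own construction. For the 587 genes at normal phosphate the count was 152 without a filter (138 shared), 225 with a replicate block (204 shared), 1126 with voom (567 shared), 296 with the GC content and length correction (249 shared), 1087 in a fit of the 2 groups, and 8 to 1059 with 1 library left out; the cause was not tested. Replicate numbers did not pair the libraries: 1 of 15 same-number pairs had a correlation above 0.1. For the 8 genes at low phosphate the count was 5 with median-ratio size factors, 2 in a fit of the 2 groups and 3 to 196 with 1 library left out, and a replicate block gave 8, of which 3 were shared, without JAL41 (limma adjusted p = 0.0697), ARP9 (0.0557), MYB77, EXO and NAD-ME2 (0.126 each); the cause was not tested. The block also ended the calls of PAP3 (0.0516), NRT3.1 (0.0554), AT3G05170 (0.0507) and AT5G60030 (0.0638) at normal phosphate and the camera calls of starvation markers between genotypes at low phosphate (0.176) and of root meristem in the interaction (0.192). The interaction count was 0 to 1 and the overlap of genotype effects 2 to 43 with 1 library left out. Camera called 44 lists and 31 families over the 5 comparisons and 0 of each with an estimated correlation (lowest adjusted p 0.0651 and 0.159); fry kept 34 of the 44 lists and 13 of the 31 families. Phosphate comparison counts stayed within 1.5 times under all other alternatives run. Of 8492 values of named genes under alternatives 8246 kept the side of the threshold, 178 no longer passed and 68 newly passed. Values that passed in neither fit counted as kept, which covers nearly all of the interaction, where the main fit called 0 genes. Nearly all values that no longer passed were in the genotype comparisons, and each phosphate comparison had 1. The pooled total therefore does not show that the genotype calls were stable. Of the values that passed in the main or the alternative fit 0 reversed. Direction was not compared where neither passed. Depth limits genes near the floor of 0.147 to 0.170 RPKM for 3 reads in 1 kb.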

Other observations

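The term tests, the purine measures and the corrected values of the families were chosen after the data were seen; the families themselves were fixed before. Among genes that rose by at least 1 on the log2 scale in wild-type roots at low phosphate, 30 of 228 genes of the response to oxidative stress were found where 10.2 were expected (Fisher exact test over 714 terms, adjusted p = 1.93e-05), many of them peroxidases such as PRX52, PER8 and PER10. Glucosinolate catabolism had 8 of 21 (0.9 expected, adjusted p = 0.000222), including the beta-glucosidases BGLU21, BGLU22 and BGLU28. Killing of cells of other organisms had 10 of 37 (1.7 expected, adjusted p = 0.000352), including TI1, HCHIB and PR4. Among genes that fell, the response to nitrate had 7 of 12 (0.4 expected, adjusted p = 8.44e-06), including NRT1.1, NRT2.1 and NIR1.

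Of the 14 families, 3 passed camera in the wild type at low phosphate. Of 79 peroxidase genes 35 rose and 18 fell (40 and 19 adjusted over the list alone; median 0.21, camera adjusted p = 0.0459, adjusted p = 0.484 with an estimated correlation). Of 135 histone genes 51 rose and 5 fell (50 and 5 adjusted over the list alone; 0.13, 0.00282, adjusted p = 0.484 with an estimated correlation), and of 36 chlorophyll genes 5 rose and 21 fell (5 and 21 adjusted over the list alone; -0.33, 0.00282, adjusted p = 0.484 with an estimated correlation). Between genotypes at normal phosphate 10 of 61 WRKY genes were lower in OX3 and 0 higher (21 and 3 adjusted over the list alone; -0.11, camera adjusted p = 5.79e-06, adjusted p = 0.164 with an estimated correlation), and 4 of 22 expansin genes were higher and 0 lower (8 and 0 adjusted over the list alone; 0.20, 0.000278, adjusted p = 0.164 with an estimated correlation). With the GC content and length correction 7 WRKY genes were lower and 1 higher (median -0.15, camera adjusted p = 3.56e-07), and 3 expansin genes were higher and 0 lower (0.16, 0.00122). The 363 ribosomal protein genes, 5 of them higher and 0 lower (0 and 0 adjusted over the list alone), had a median of 0.20 (camera adjusted p = 2.49e-20, adjusted p = 0.296 with an estimated correlation), and 0.14 with 0 genes called with the GC content and length correction.

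The other 6 families that passed camera at normal phosphate were chlorophyll (8 higher and 1 lower, 12 and 1 adjusted over the list alone; adjusted p = 8.65e-05, adjusted p = 0.164 with an estimated correlation) and extensin or proline-rich (3 and 4, 4 and 10 adjusted over the list alone; 0.000278, adjusted p = 0.265 with an estimated correlation). Cytochrome P450 (1 and 3, 2 and 9 adjusted over the list alone; 0.000721, adjusted p = 0.265 with an estimated correlation) and glycosyltransferase (0 and 10, 1 and 16 adjusted over the list alone; 0.00697, adjusted p = 0.159 with an estimated correlation) passed too. Receptor kinase (0 and 10, 0 and 6 adjusted over the list alone; 0.000134, adjusted p = 0.164 with an estimated correlation) and ABC transporter (0 and 0, 0 and 0 adjusted over the list alone; 0.000278, adjusted p = 0.265 with an estimated correlation) no longer passed with the GC content and length correction (0.402 and 0.32).

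Sequence composition moved with genotype. At normal phosphate 10.9% of the 539 tested genes whose richest 50-base window was over 0.9 A and G were called lower in OX3 and 0.2% higher, against 0.5% and 2.1% of the 2662 genes at up to 0.7. Median differences were -0.09 and 0.07 for these sets at normal phosphate and -0.07 and 0.03 at low phosphate. In the low phosphate comparisons the Spearman correlation with that share was 0.015 in the wild type and 0.054 in OX3. After length and GC content were regressed out it was -0.122 and -0.077 for the genotype differences at normal and low phosphate.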
